A study of Drosophila melanogaster with 38 samples.

How the data were processed

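The libraries came from stage 15 Drosophila melanogaster embryos whose mothers carried RNA interference (RNAi) against mof or a control RNAi, per the labels, and which had been sorted into males and females. Per the labels' protocols, 6000 embryos per sample were dissociated with a loose pestle, the filtered cells were incubated with 500 µM 4-thiouridine (4sU) for 5 min at 25 °C, and libraries were made with a stranded kit that removes ribosomal RNA. TT-seq sequences the RNA labelled in that pulse, which is newly made RNA, and the total RNA-seq libraries measure the RNA present at that time. The labels gave 8 groups, for 2 assays, 2 sexes and 2 RNAi genotypes, and 38 libraries. Every group had replicates 1 to 5, except TT-seq mof RNAi females (replicates 2 to 5) and RNA-seq mof RNAi females (replicates 1, 3, 4 and 5). The labels do not say whether the replicates came from separate embryo collections, so p-values measure the spread between these samples, which may be technical.

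The authors deposited 4 tables, for TT-seq males, TT-seq females, RNA-seq males and RNA-seq females, each with 1 value per gene and library. Per their deposited names these values are DESeq2-normalized counts, a signal that scales with reads per gene. Per the submitters' processing notes the tools were cutadapt 2.8, STAR 2.7.4a, SAMtools 1.20, featureCounts and DESeq2 with the build dm6; the role of each, and the strand setting of the counting, are not given in the sources used here. The deposited signal was checked for its step size: 100% of the values of every library were whole multiples of 1 step, within a tolerance of 0.001, so whole reads and depth could be recovered. Median-of-ratios size factors recomputed from those reads matched the deposited scaling in each table, which was therefore scaled on its own. All tests ran within 1 table, and comparisons between tables were tested only as differences of within-table changes. The untested X levels of males against female controls are the exception that crosses tables. Gene positions and biotypes came from the deposited annotation, with 17737 genes, of which 13931 code for proteins and 2671 lie on the X. Since the strand setting is not stated, genes that overlap another gene on either strand are uncertain; among the genes named here these are Adgf-A, arm, aub, Clamp, Corp, cort, Cyp4p1, Cyp4p2, egr, elg1, Fign, futsch, GatB, Grip128, hfw, Hsp83, Ir76a, Kif3C, l(1)G0193, l(2)41Ab, moody, mRpS9, mRRF1, msl-2, msl-3, mthl14, ndl, Nprl2, pn, rec, RhoGAP1A, roX1, RpS5a, schlank, Seipin, Spt6, Sxl, Syx1A, TM4SF, y and Zw. The neighbouring relatives Cyp4p1 and Cyp4p2 may also share reads. Signal tracks, transcription rate tables and other deposited items were not analysed here.

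Recovered depth was 12.2 to 22.8 M reads in genes per TT-seq library and 11.9 to 33.0 M per RNA-seq library. No pair of libraries of a group matched within counting noise: the lowest chi-square per degree of freedom, over genes with at least 20 reads in the pair, was 12.9.

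Genes were tested with limma 3.58.1 in R 4.3.3, on log2(normalized count + 1), for genes with a mean of at least 10 over the libraries of the table, with a mean-variance trend, Benjamini-Hochberg adjustment and a threshold of 0.05. Every fold change is mof RNAi minus control on the log2(value + 1) scale, which understates changes of low genes. Deviations were taken from the mean of each gene over all libraries of its table. In each library the median deviation of X genes minus that of genes on 2L, 2R, 3L and 3R was taken (the X shift). The group means were compared with exact two-sided permutation tests, whose smallest p is 0.00794 for 5 against 5 and for 5 against 4 libraries. Fisher's exact test compared X and autosomal genes among those that fell. Genes are not independent replicates, so its p-values and intervals describe where the calls lie and not the spread between libraries. Differences of the X shift between sexes or assays were tested by permuting residuals 100000 times, where the smallest p is 1e-05, and differences of single genes with limma interaction terms. Chromosome arms were compared by exact permutation tests adjusted over 6 arms.

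Before the data were examined the tests above, the naming rule and 28 lists of genes were fixed. The lists were for the MSL and NSL complexes, sex determination, X genes long studied for dosage compensation, Y genes, RNA polymerase II factors, ribosomal, mitochondrial ribosomal and oxidative phosphorylation proteins, heat shock, cell death, cell cycle, Hox, ecdysone, maternal, early patterning and immune peptide genes, and for markers of neurons, glia, muscle, hemocytes, fat body, trachea, epidermis, gut, salivary gland, germ line and yolk with amnioserosa. Of their members, 8 matched no annotated gene. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The named genes follow a rule: mof, the MSL proteins, roX1, roX2 and Clamp; per table the 5 X and 5 autosomal protein-coding genes with the largest fall, and the 5 autosomal and 3 X genes with the largest rise, among those past the threshold, with a mean of at least 50, a name that is not a CG or CR number and every mof RNAi library beyond every control library; the 2 tested members with the smallest p of each list with a member past the threshold; and the 4 genes with the smallest p per interaction.

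Groups share replicate numbers. The deviations of same-numbered control and mof RNAi libraries from their group means correlated at 0.193 to 0.712 across genes in the 18 pairs, so the numbers pair the samples. In 16 pairs the mof RNAi library correlated best with its own number; mof 4 correlated better with control 3 in RNA-seq males (0.581 against 0.239) and in RNA-seq females (0.354 against 0.267). This pairing is read from the values, since the labels do not state what a number marks, and fits with the number as a block are given as blocked values.

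The alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, recentring of each library on autosomal genes, quantile normalization, no variance trend, library weights, the replicate block, an estimated correlation or fry for lists, means in place of medians, protein-coding genes only, and leaving out each library. After the data were seen, edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads with and without the block, X shifts without overlapping genes, and lists on autosomes only were added. edgeR on the recovered reads called 613 genes in TT-seq males, 240 in TT-seq females, 2027 in RNA-seq males and 638 in RNA-seq females.

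The scripts were tested on simulated tables with an X shift of -0.5, in females as in males, and 200 changed genes. The changed genes were autosomal with a mean of at least 50, and no effect of the replicate number was simulated. The shifts recovered were -0.49 (TT-seq males, 10706 genes), -0.49 (TT-seq females, 10727), -0.50 (RNA-seq males, 10923) and -0.49 (RNA-seq females, 10616). In the same order, genes lowered by 2 on the log2 scale were called in 94%, 100%, 98% and 100% of cases, and genes lowered by 1 in 64%, 58%, 92% and 84%. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.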

Results

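The data were 38 libraries of stage 15 Drosophila embryos, male or female, from mothers with mof RNAi or control RNAi. RNA-seq read the RNA present and TT-seq the RNA made in a 5 min pulse of 4sU. Groups held 5 libraries, except mof RNAi females with 4 in TT-seq and 4 in RNA-seq. Mean depth per group was 15.6 to 17.6 M reads in genes for TT-seq and 24.7 to 28.9 M for RNA-seq. The lowest library, an RNA-seq female control, held 11.9 M. The labels do not state that replicates are separate collections, so p-values measure spread between these samples only. The 4 tables, 1 per assay and sex, were normalized separately, so levels are compared within a table, except for X genes of males against female controls. All fold changes are log2, mof RNAi minus control, ± standard error. They are relative to the typical gene of a table, so a change shared by all genes would go unseen, and the role of spike-ins in these tables is not stated.

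The RNAi target mof, which encodes the acetyltransferase of histone H4 in the MSL and NSL complexes, fell in all 4 tables, and every mof RNAi library lay below every control. In RNA-seq males it fell by 2.79 ± 0.15, from a mean of 2214 ± 450 (SD, n = 5) to 317 ± 50.1 (n = 5; limma adjusted p = 7.31e-07), which is 6.92-fold. In RNA-seq females it fell by 1.39 ± 0.15, from 1034 ± 174 (n = 5) to 396 ± 71.9 (n = 4; limma adjusted p = 0.000154). In TT-seq males it fell by 1.89 ± 0.22 (1026 ± 336 to 267 ± 42.6, n = 5 and 5; limma adjusted p = 0.000491). In TT-seq females it fell by 1.11 ± 0.17 (656 ± 133 to 300 ± 29.6, n = 5 and 4; limma adjusted p = 0.00443). The gene lies on the X, so its male values include any change shared by X genes.

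**Figure D1:**
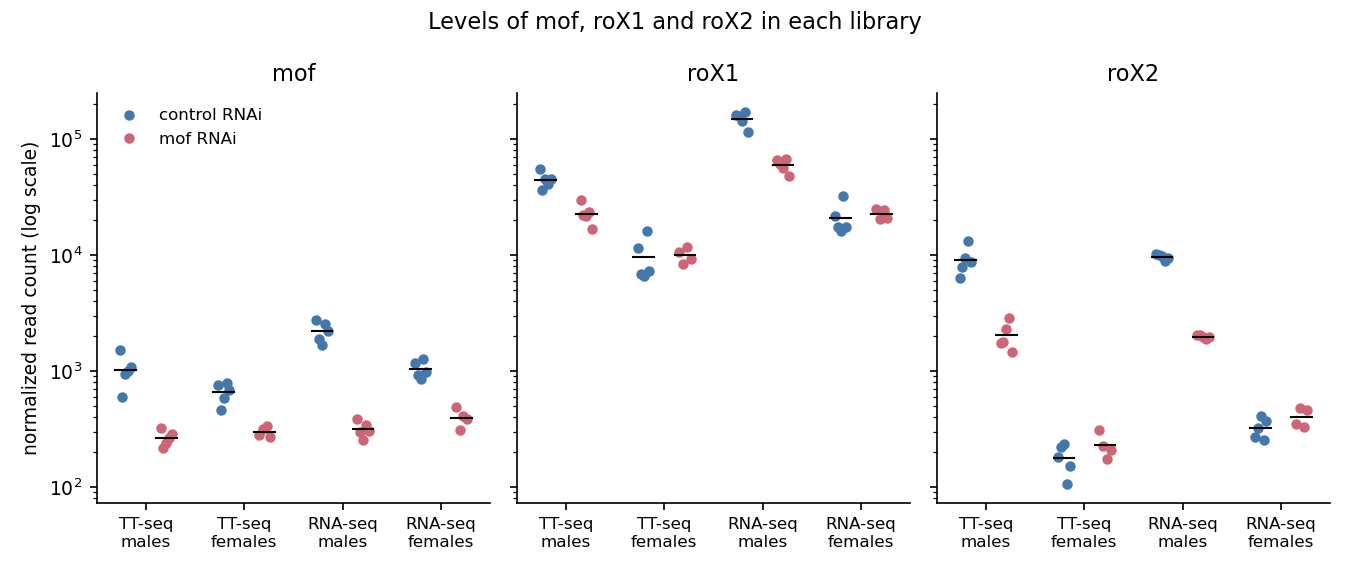
Normalized counts (log scale) of mof, roX1 and roX2 in each library (points, n = 4 or 5 per group) with group means (bars), by table and RNAi. In RNA-seq males roX2 went from a mean of 9670 to 1982 and roX1 from 149280 to 59757, while in females neither gene passed the test.

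The non-coding RNAs roX1 and roX2, which assemble with the MSL proteins, fell in males and did not pass in females. The sex difference passed for roX2 in both assays and for roX1 in RNA-seq, but not for roX1 in TT-seq (limma adjusted p = 0.11; blocked 0.00875; 0.0429 without female control 4). In TT-seq males roX2 fell by 2.16 ± 0.21 (9106 ± 2562 to 2028 ± 551, SD, n = 5 and 5; limma adjusted p = 0.00019) and roX1 fell by 0.98 ± 0.15 (44609 ± 6702 to 22716 ± 4595; limma adjusted p = 0.00315). In RNA-seq males roX2 fell by 2.28 ± 0.059 (limma adjusted p = 5.81e-10) and roX1 fell by 1.32 ± 0.12 (limma adjusted p = 2.63e-05). In females roX1 had a limma adjusted p of 0.85 in TT-seq and 0.763 in RNA-seq, and roX2 of 0.537 and 0.436. The reads of roX1 are uncertain because another gene overlaps it.

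Among the MSL proteins msl-1 rose in RNA-seq males by 0.29 ± 0.076 (limma adjusted p = 0.022) and msl-3 by 0.30 ± 0.087 (limma adjusted p = 0.0339). Both rises depended on single libraries: msl-1 did not pass without control 2, control 3, mof 1 or mof 5 (limma adjusted p = 0.0502 to 0.0576), nor msl-3 without control 2, 3 or 5 or mof 1, 2 or 5 (0.0661 to 0.0886). After recentring on autosomal genes msl-1 was 0.22 (limma adjusted p = 0.0767) and msl-3 0.23 (limma adjusted p = 0.104). In RNA-seq males msl-2 was 0.27 ± 0.094 (limma adjusted p = 0.0718; blocked 0.0233; 0.0191 without control 4), and the RNA helicase gene mle 0.15 (limma adjusted p = 0.222; blocked 0.0482). In TT-seq males msl-1 was 0.31 ± 0.12 (limma adjusted p = 0.173; blocked 0.0367), msl-2 0.41 ± 0.13 (limma adjusted p = 0.103; blocked 0.0203), msl-3 0.32 (limma adjusted p = 0.317) and mle 0.17 (limma adjusted p = 0.542). The zinc-finger gene Clamp passed in no table, with 0.14 in TT-seq males and 0.14 in RNA-seq males. In females none of these 5 genes passed; msl-1 was -0.058 in TT-seq and 0.048 in RNA-seq.

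In males the X as a whole fell against the autosomes after mof RNAi. In TT-seq males the X shift was -0.62 ± 0.024, a fall of 34.8%, and in RNA-seq males -0.55 ± 0.027, a fall of 31.6% (n = 5 and 5 libraries; permutation p = 0.00794 for each, the smallest possible). In females the X shift was 0.0031 ± 0.012 in TT-seq (permutation p = 0.786) and -0.014 ± 0.014 in RNA-seq (permutation p = 0.317; n = 5 and 4). Of the 1727 X genes tested in TT-seq males, 93.1% had a fold change below 0, against 32.4% of 8974 autosomal genes; in RNA-seq males the shares were 92.7% and 34.8%. Paired by replicate number, the male p was 0.0625 in TT-seq and 0.0625 in RNA-seq, the smallest possible with 5 pairs. The paired female shift was 5e-04 ± 0.0077 in TT-seq and -0.011 ± 0.0024 in RNA-seq. The RNA-seq value had a sign-flip permutation p of 0.125, the smallest possible with 4 pairs. The TT-seq female value changed sign without control 3 (-0.0040) or mof 5 (-0.0030), and was 0 without mof 4.

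**Figure D2:**
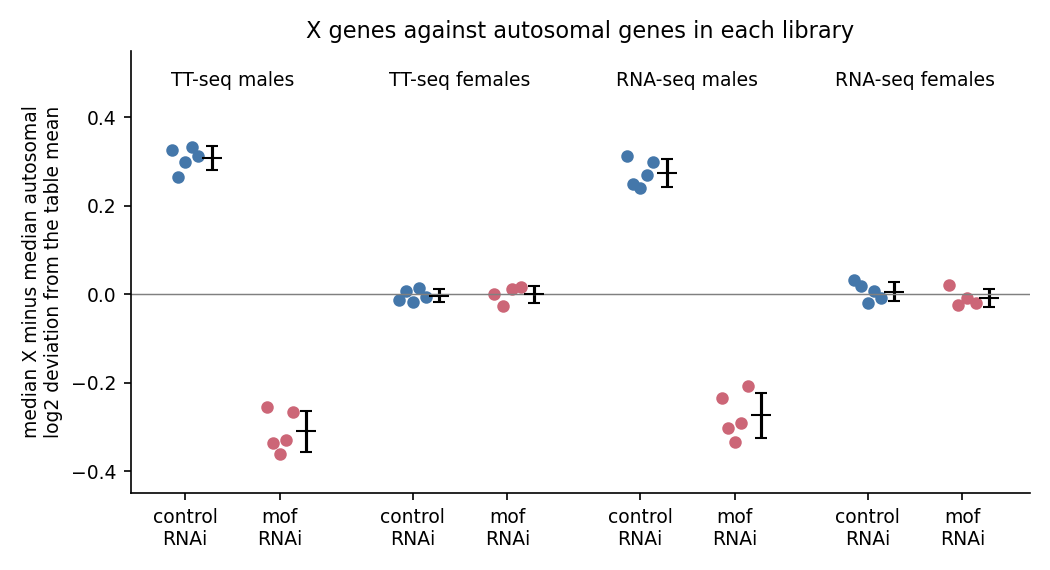
Median log2 deviation of X genes minus that of autosomal genes in each library (points) with mean and SD, for 8 groups (n = 4 or 5). Control males averaged 0.31 in TT-seq and 0.27 in RNA-seq, and mof RNAi males -0.31 and -0.27, while female groups lay near 0. Deviations are from the mean of each gene over all libraries of its table, which centres the groups of a table on 0. Only the distance between the groups of a table therefore carries the result.

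Against female controls of the same assay, X genes of control males stood at 95.8% in TT-seq and 91.8% in RNA-seq, relative to autosomal genes. In mof RNAi males they stood at 61.6% in TT-seq and 62.2% in RNA-seq, and in mof RNAi females at 99.9% and 98.7%. These levels cross tables that were normalized separately, and no test was run on them.

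In TT-seq males the sodium leak channel gene na fell most among named X genes (-2.80 ± 0.16), from 2299 ± 279 to 332 ± 68.7 (SD, n = 5 and 5; limma adjusted p = 6.45e-07), which is 6.98-fold. The GATOR1 gene Nprl2 fell by 2.44 ± 0.25 (limma adjusted p = 0.00023), and so did the Hsc70-interacting relative HIP-R (-2.02 ± 0.30), pn (-2.01 ± 0.30) and the lipid droplet gene Seipin (-2.01 ± 0.25). On autosomes the largest falls were of rec, an MCM-like gene of meiotic recombination (-1.92 ± 0.32), and of the translesion polymerase gene Rev1 (-1.77 ± 0.20). The ER degradation gene Der-2 (-1.71 ± 0.21), the COP9 signalosome gene CSN7 (-1.61 ± 0.20) and the nucleotidase gene cN-IIIB (-1.56 ± 0.33) also fell. The cytochrome P450 gene Cyp4p2 rose by 0.70 ± 0.12 (limma adjusted p = 0.00565); its relative Cyp4p1 lies beside it, and reads may be shared. The protease gene ndl rose by 0.87 ± 0.23 (limma adjusted p = 0.0443), but not without any 1 of the 10 libraries (0.055 to 0.128). The RFC-like gene elg1 rose by 0.53 ± 0.14 (limma adjusted p = 0.0474), again not without any 1 of the 10 (0.0617 to 0.137). The V-ATPase gene Vha68-1 rose by 0.56 ± 0.13 (limma adjusted p = 0.0251), not without control 1 or 4 or mof 2, 3 or 5 (0.0505 to 0.077). The palmitoyltransferase gene Hip14 rose by 0.43 ± 0.11 (limma adjusted p = 0.0323), and kept its call only without control 2 or control 5 (0.0622 to 0.0937 otherwise). After recentring ndl (limma adjusted p = 0.0519), elg1 (0.0719) and Hip14 (0.0601) did not pass.

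In TT-seq males 517 of 10800 genes passed, of which 498 fell and 19 rose. The X held 384 of the falls, or 77.1%: 22.2% of tested X genes fell against 1.27% of autosomal genes (odds ratio 22.2, 95% interval 17.8 to 27.9; Fisher p = 7.21e-214). Genes are not independent replicates, so this interval and p describe only where the calls lie. On autosomes 114 genes fell and 17 rose, and 1 X gene rose. With the replicate number as a block 1730 genes passed, with 889 X falls, 270 autosomal falls and 563 autosomal rises. The blocked fit was not recentred, so how many of its rises rest on the scaling was not tested. Recentring on autosomal genes gave 853 genes, 839 falling and 14 rising, with 660 X falls and 179 autosomal falls. The count dropped by more than a factor of 1.5 without control 1 (257), control 4 (325), control 5 (312), mof 2 (252), mof 3 (248), mof 4 (292) or mof 5 (306).

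In TT-seq females the X genes with the largest falls were Nprl2 (-2.35 ± 0.22; limma adjusted p = 0.000331, n = 5 and 4) and the gamma-tubulin complex gene Grip128 (-1.95 ± 0.17). Seipin (-1.76 ± 0.23), HIP-R (-1.73 ± 0.19) and the molybdenum cofactor sulfurase gene mal (-1.54 ± 0.18) also fell, and na fell by 0.86 ± 0.14 (limma adjusted p = 0.00579). On autosomes the ionotropic receptor gene Ir76a fell by 5.07 ± 0.37, from a mean of 59.3 to 0.916 (limma adjusted p = 3.64e-05). The tachykinin receptor gene TkR99D fell by 2.44 ± 0.28 and CSN7 fell by 2.17 ± 0.15 (318 ± 20.2 to 70.5 ± 8.72, SD). The receptor gene GABA-B-R3 (-2.07 ± 0.25) and Der-2 (-1.80 ± 0.18) fell as well. The capsid gene Arc1 rose by 0.68 ± 0.16 (limma adjusted p = 0.044), but not without any 1 of the 9 libraries (0.0565 to 0.169). The adenosine deaminase gene Adgf-A rose by 0.55 ± 0.13 (limma adjusted p = 0.0481), a call that held only without control 3 (0.0631 to 0.169 otherwise). With quantile normalization Arc1 (limma adjusted p = 0.0561) and Adgf-A (0.0754) did not pass.

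In TT-seq females 209 of 10785 genes passed, 202 falling and 7 rising. On the X 41 genes fell, 2.30% of those tested, and on autosomes 161, or 1.81% (odds ratio 1.28, 95% interval 0.879 to 1.82; Fisher p = 0.182). The odds ratio was above 1 with a Fisher exact p from 0.00126 to 0.0346 without control 1 (1.99), control 2 (Fisher exact p = 0.0209), control 4 (1.56), control 5 (1.82), mof 2 (1.81), mof 3 (1.72), mof 4 (1.61) or mof 5 (1.56). These p-values take genes as independent, while the X shift between the libraries was 0.0031 (permutation p = 0.786). The replicate block gave 850 genes, with 97 X falls, 415 autosomal falls, 53 X rises and 280 autosomal rises, and library weights gave 612 genes, 492 falling and 120 rising. Without control 1 the count of genes was 124, without control 5 112, without mof 2 119 and without mof 4 122.

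In RNA-seq males na fell by 2.91 ± 0.099, from 5140 ± 671 to 680 ± 60.1 (SD, n = 5 and 5; limma adjusted p = 7.38e-09), which is 7.53-fold. On the X pn (-2.47 ± 0.21), Nprl2 (-2.27 ± 0.16) and the G protein gene Gbeta5 (-2.05 ± 0.22) fell (limma adjusted p = 2.24e-05, 8.89e-06 and 9.04e-05). On autosomes Ir76a fell by 3.91 ± 0.30, from 185 ± 15.3 to 12.4 ± 6.21, which is 15.1-fold (limma adjusted p = 1.45e-05). The recombination gene rec (-2.25 ± 0.27), the microtubule severing gene Fign (-2.25 ± 0.40) and mRRF1, for ribosome recycling in mitochondria (-2.25 ± 0.31), fell. The amidotransferase gene GatB fell by 2.03 ± 0.28 (limma adjusted p = 0.000467). Cyp4p1 rose by 0.84 ± 0.13, from 337 ± 48.0 to 604 ± 75.8 (limma adjusted p = 0.000778), and the ABC transporter gene Mdr50 by 0.80 ± 0.15. The protease gene ndl rose by 0.76 ± 0.18 (limma adjusted p = 0.0138), the decay factor gene Smg5 by 0.57 ± 0.078 (0.00043) and the receptor gene mthl14 by 0.55 ± 0.12 (0.00961).

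In RNA-seq males 1890 of 10994 genes passed, 1318 falling and 572 rising. On the X 894 of 1763 tested genes fell, or 50.7%, and 1 rose; on autosomes 421 of 9131 fell, or 4.61%, and 563 rose (odds ratio of falling on the X 21.3, 95% interval 18.5 to 24.4). Recentring each library on autosomal genes lowered the autosomal rises from 563 to 148, as all genes moved by 0.073. The 563 genes had a median of 0.29 before and 0.22 after recentring, so most calls, but not most of the change, depended on the scaling. The replicate block gave 2843 genes with 1204 autosomal rises. The blocked fit was not recentred, so how many of these rises rest on the scaling was not tested. Without mof 2 the count of genes was 1243.

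**Figure D3:**
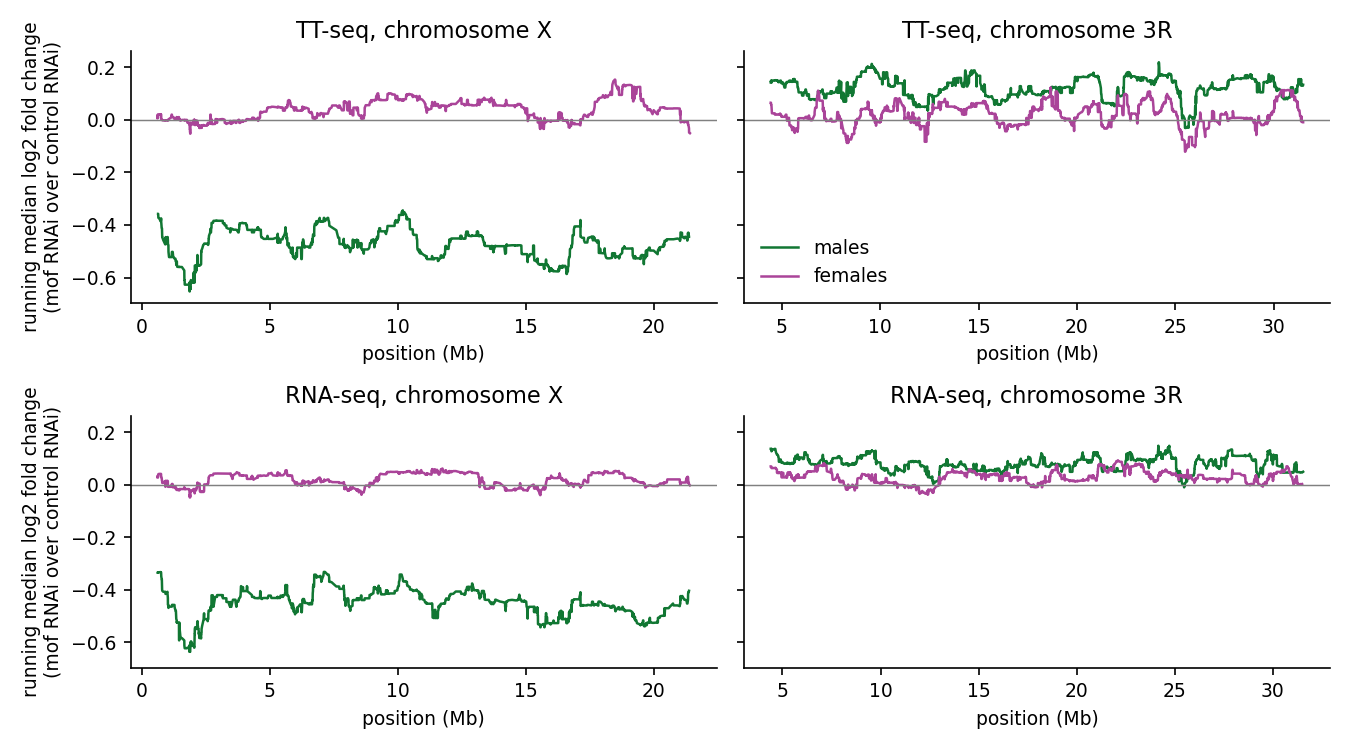
Running median over neighbouring genes of the log2 fold change along the X and 3R (Mb), in TT-seq and RNA-seq, for males and females. In males the X curve stayed between -0.65 and -0.34 in TT-seq and between -0.64 and -0.33 in RNA-seq; the 3R curves of both sexes lay between -0.12 and 0.22, and the X curves of females between -0.053 and 0.15.

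In RNA-seq females the X genes with the largest falls were Nprl2 (-2.39 ± 0.18; limma adjusted p = 2.14e-05, n = 5 and 4), RhoGAP5A (-2.13 ± 0.18), pn (-2.10 ± 0.31), Grip128 (-2.10 ± 0.16) and HIP-R (-1.80 ± 0.22). The channel gene na fell by 1.18 ± 0.071 (limma adjusted p = 3.17e-06). On autosomes Ir76a fell by 4.76 ± 0.54 (132 ± 20.8 to 5.90 ± 6.43, SD; limma adjusted p = 0.00023), and so did Fign (-2.97 ± 0.31), GatB (-2.86 ± 0.22), TkR99D (-2.46 ± 0.43) and rec (-2.26 ± 0.21). The tetraspanin gene TM4SF rose by 1.03 ± 0.20 (limma adjusted p = 0.00957), the kinesin gene Kif3C on chromosome 4 by 0.94 ± 0.19 (0.0106) and l(2)41Ab by 0.80 ± 0.15 (0.00833). The elongation factor gene eEF1alpha2 rose by 0.52 ± 0.12 (limma adjusted p = 0.0221), not without control 1, mof 1 or mof 5 (0.0588 to 0.0763). Cyp4p1 rose by 0.49 ± 0.12 (limma adjusted p = 0.0289), not without control 1 or 5 or mof 1, 4 or 5 (0.0578 to 0.09). On the X RhoGAP1A rose by 0.36 ± 0.081 (limma adjusted p = 0.0215), not without mof 1, 3 or 4 (0.0663 to 0.0786). The tweety gene tty rose by 0.28 (limma adjusted p = 0.0481), not without control 2, 3, 4 or 5 or mof 1, 4 or 5 (0.0641 to 0.162). With quantile normalization RhoGAP1A (limma adjusted p = 0.0735) and tty (0.115) did not pass, nor did tty after recentring (0.0512).

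In RNA-seq females 618 of 10678 genes passed, 579 falling and 39 rising. On the X 105 fell, 5.90% of those tested, and on autosomes 474, or 5.39% (odds ratio 1.10, 95% interval 0.876 to 1.37; Fisher p = 0.391). On autosomes 31 rose, and 117 with the replicate block.

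Autosomal genes that fell in females overlapped with those that fell in males. In RNA-seq 303 autosomal genes fell in both sexes, of 414 in males and 474 in females, where independent calls would share 22.4. In TT-seq 77 did, of 112 and 160, with 2.04 by chance. Between assays 111 autosomal genes fell in TT-seq males and RNA-seq males (5.26 by chance) and 142 in TT-seq females and RNA-seq females (8.62 by chance). On the X 368 genes fell in both assays in males, where 202 were due by chance. The sexes share no libraries, but they share replicate numbers, and whether same-numbered males and females were collected together is not stated. Nor is it stated whether TT-seq and RNA-seq libraries came from the same embryos. The chance values between sexes and between assays assume independent samples, so they may be too low.

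**Figure D4:**
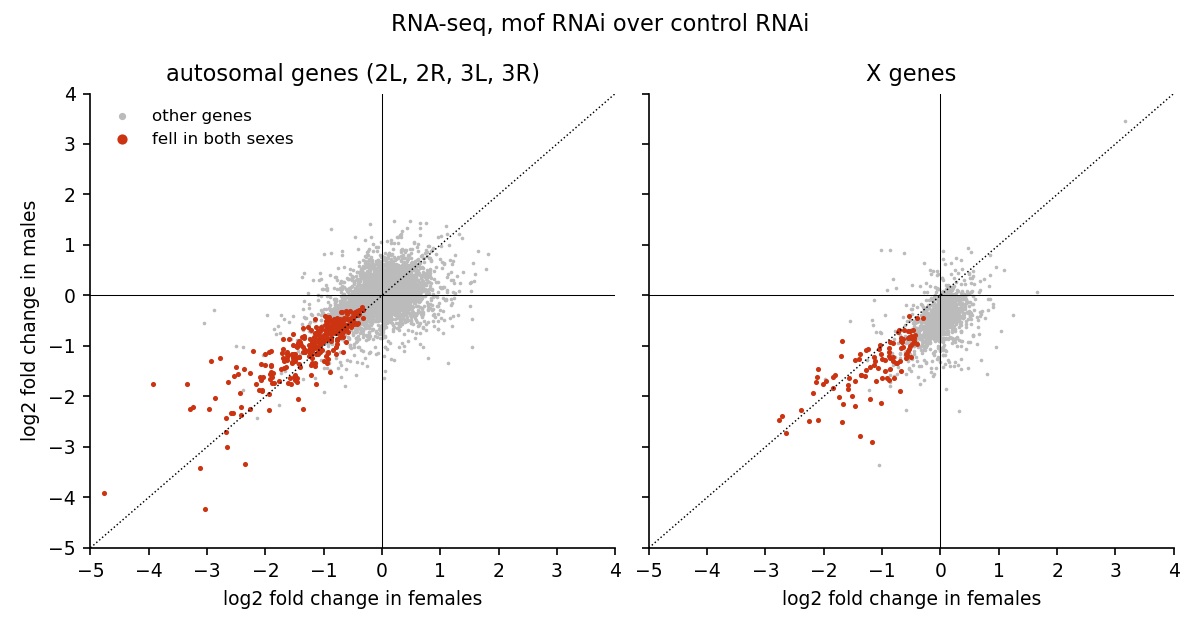
RNA-seq log2 fold change in males against females for 8756 autosomal (left) and 1725 X genes (right), 1 point per gene, with a dotted diagonal. Genes that fell in both sexes (red) numbered 303 and 100, and the X points are shifted below the diagonal.

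Between the sexes the X shift differed by -0.62 in TT-seq (95% interval -0.67 to -0.57, permutation p = 1e-05) and by -0.53 in RNA-seq (-0.59 to -0.47, permutation p = 1e-05). These permutations ignored the replicate numbers. With control and mof RNAi paired by number within each sex, the differences were -0.62 and -0.54 (permutation p = 0.00794 for each, the smallest possible). All tests between the sexes take males and females as independent samples. The gene na fell more in males than in females, with a difference of -1.95 ± 0.21 in TT-seq (limma adjusted p = 8.09e-05) and -1.73 ± 0.12 in RNA-seq (limma adjusted p = 6.91e-08). The X gene l(1)G0193 differed by -1.16 ± 0.16 in TT-seq and -0.98 ± 0.094 in RNA-seq (limma adjusted p = 0.00124 and 4.77e-06). In RNA-seq the integrin gene mys differed by -0.62 ± 0.058, mof by -1.41 ± 0.22 (limma adjusted p = 0.000595), roX1 by -1.47 ± 0.22 and roX2 by -2.60 ± 0.18. In TT-seq roX2 differed by -2.55 ± 0.34 (limma adjusted p = 0.00082). Also in TT-seq hfw differed by -0.91 ± 0.16 (limma adjusted p = 0.0171), not without male control 3 or female mof 4 or 5 (0.0501 to 0.0649). The ceramide synthase gene schlank differed by -0.80 ± 0.15 (limma adjusted p = 0.0357). It did not without male control 3 or 5, male mof 2, 3, 4 or 5, female control 1, 3, 4 or 5, or female mof 2, 4 or 5 (0.0525 to 0.125). In TT-seq mof differed by -0.78 (limma adjusted p = 0.288; blocked 0.0218) and roX1 by -1.12 (0.11; blocked 0.00875; 0.0429 without female control 4). In RNA-seq msl-1 differed by 0.24 (limma adjusted p = 0.223; blocked 0.0332).

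By gene, 28 of 10606 differed between the sexes in TT-seq, of which 27 were X genes with the lower value in males, and 461 did with the replicate block. The count was 64 without male control 2. It was 10, 5 and 8 without male control 1, 3 and 5, and 8, 9, 9 and 8 without male mof 2, 3, 4 and 5. Leaving out female control 1, 2, 3, 4 or 5 gave 9, 9, 12, 10 and 10, and female mof 2, 3, 4 or 5 gave 7, 16, 5 and 5. In RNA-seq 455 of 10577 genes differed, 408 with the lower value in males, of which 407 lie on the X, and the block gave 734.

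Between assays the X shift of males differed by -0.069 (95% interval -0.14 to 0.0014; permutation p = 0.0574; paired p = 0.00794), and that of females by 0.017 (permutation p = 0.305). The paired test pairs control with mof RNAi within an assay. All these tests take the assays as independent samples, so their p-values do not hold if the assays share embryos. The male difference had a p below the threshold without TT-seq control 2 (-0.082), TT-seq mof 1 (-0.080), TT-seq mof 5 (-0.082), RNA-seq control 1 (-0.078), RNA-seq control 5 (-0.076) or RNA-seq mof 3 (-0.083). By gene, 0 of 10541 differed between the assays in males by limma, and 0 with the replicate block. At an unadjusted limma p below 0.05 there were 57, and 220 with the block. Both are far below the share of 0.05 that chance alone would give. The test was therefore conservative, and the 0 does not show that the assays changed alike. The fall of mof was the smaller in TT-seq males by 0.90 ± 0.28 (limma adjusted p = 1). edgeR was not run on this interaction.

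Ribosomal protein genes and X genes long studied for dosage compensation were the lists called in TT-seq males. Of 13 tested studied X genes 4 fell (5 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 1.03e-05; adjusted p = 0.0679 with an estimated correlation). All 13 lie on the X, so this call restates the male X shift, and mof is 1 of the 4. Zw, which encodes glucose-6-phosphate dehydrogenase, fell by 0.94 ± 0.19 (limma adjusted p = 0.0143). Of 88 ribosomal protein genes 76 lay above 0, with a median of 0.24 and 0 past the test (camera adjusted p = 0.000212, adjusted p = 0.97 with an estimated correlation). Part of this rise is the scaling. Only 32.4% of all tested autosomal genes lay below 0, and after recentring the ribosomal median was 0.15. The ribosomal call was lost without control 2 (0.0659), control 4 (0.399) or mof 2 (0.052). The count of 2 called lists became 1 without control 2, control 4 or mof 2, 6 without control 5 and 5 without mof 4. In TT-seq males the MAP1B relative futsch fell by 0.74 ± 0.13 (limma adjusted p = 0.0067), the only neuron marker of 16 to pass. The glial receptor gene moody fell by 0.64 (limma adjusted p = 0.0302), not without control 3, 4 or 5 or mof 2, 3 or 5 (0.0569 to 0.0907). The cell cycle gene CycD fell by 0.57 ± 0.13 (limma adjusted p = 0.02), not without control 1 or 3 or mof 2 or 3 (0.0505 to 0.0651). The TFIID gene Taf8 fell by 0.96 (limma adjusted p = 0.041), not without control 1, 3, 4 or 5 or mof 2, 3 or 4 (0.0536 to 0.114), nor with quantile normalization (0.0737). With the block RnrS (0.66; limma adjusted p = 0.142, blocked 0.0012), Rcd1 of the NSL complex (0.40; 0.143, blocked 0.0124) and the kinase gene Cdk7 (-0.57; 0.114, blocked 0.0264) also passed, as Cdk7 did after recentring (0.0376). Of the mitochondrial ribosomal genes, 2 of 72 fell and 0 did when adjusted over the list alone. The 2 that fell lie on the X, as do futsch, moody, CycD, Taf8 and Cdk7. Their falls therefore include any change shared by male X genes. Over all tested X genes the median was -0.48 (quartiles -0.70 and -0.29). The other lists with members past were the MSL list (3 fell of 8; 2 rose and 3 fell over the list alone), the NSL list (1 of 7, mof) and Y genes (1 rose of 2; 2 over the list alone). In the MSL list the median was 0.15 while the mean was -0.46 and the test pointed down. With autosomal members and background 7 lists were called. The MSL, NSL and oxidative phosphorylation (camera adjusted p = 0.035 for each), ribosomal (0.000616) and cell cycle (0.0133) lists pointed up, and early patterning (0.00779) and yolk (0.035) down. For all 7 the adjusted p = 0.955 with an estimated correlation. The lists of cell death, ecdysone, immune peptide, glia, muscle, fat body, trachea, midgut and salivary gland genes changed direction with the scaling. Recentring moved all genes by 0.098, more than each of these medians, so the turns follow from that shift alone.

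In TT-seq females genes for ribosomal proteins had the clearest list result: 86 of 88 lay above 0, with a median of 0.42 (camera adjusted p = 3.54e-31; adjusted p = 0.852 with an estimated correlation). None passed over all genes, and 79 rose when adjusted over the list alone. Oxidative phosphorylation genes had 61 of 69 above 0 and a median of 0.23 (camera adjusted p = 9.89e-06; adjusted p = 0.852 with an estimated correlation). All 19 muscle markers lay above 0, with a median of 0.49 (camera adjusted p = 0.00197; adjusted p = 0.852 with an estimated correlation). Hemocyte markers had 11 of 13 above 0, 5 risen over the list alone and a median of 0.46 (camera adjusted p = 0.00153; adjusted p = 0.852 with an estimated correlation). Mitochondrial ribosomal genes had 60 of 72 above 0 and a median of 0.19 (camera adjusted p = 0.000702; adjusted p = 0.852 with an estimated correlation), a call lost without control 2 (0.0571) or mof 3 (0.0507). With the replicate block 8 lists were called in place of 5, adding heat shock (median -0.45; camera adjusted p = 0.0725, blocked 1.24e-10), cell cycle (0.0733, blocked 0.00816) and early patterning (0.198, blocked 0.0255). For these 3 the blocked adjusted p = 0.821 with an estimated correlation. The NSL gene Rcd5 was 0.34 (limma adjusted p = 0.495; blocked 0.0311). The only list member past over all genes was mof, in the MSL, NSL and studied X lists. The maternal list had 1 fall over the list alone and a median of 0.11 with a mean of -0.022. The NSL and studied X lists changed direction with the scaling.

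In RNA-seq males the 1 called list was that of X genes long studied for dosage compensation, of which 7 of 13 fell (7 over the list alone), with a median of -0.39 (camera adjusted p = 2.62e-06; adjusted p = 0.463 with an estimated correlation). This call too restates the male X shift, and mof is 1 of the 7. Among these Zw fell by 0.98 ± 0.15 (limma adjusted p = 0.000699) and the beta-catenin gene arm fell by 0.65 ± 0.066 (6.27e-05). Falls within other lists were mostly of X genes. Of 72 mitochondrial ribosomal genes 12 fell, 10 of them on the X, and 1 rose; mRpL38 fell by 0.72 ± 0.084 and mRpL22 fell by 0.51 ± 0.083. Of 69 oxidative phosphorylation genes 11 fell, 10 of them on the X, and 2 rose; the complex I genes ND-24 (-0.80 ± 0.11) and ND-20 (-0.57 ± 0.078) were among them. Of 32 polymerase II factors 5 fell, all on the X, and 2 rose; the elongation factor gene Spt6 fell by 0.45 ± 0.083 and Taf8 fell by 0.65 ± 0.16. Of 90 ribosomal genes 3 fell, and 0 over the list alone, with RpS5a at -0.28 ± 0.063 (limma adjusted p = 0.00995). Among markers futsch fell by 0.79 ± 0.081 and moody fell by 0.58 ± 0.085, and the cell death gene Corp fell by 1.00 ± 0.22 (limma adjusted p = 0.00753). The ribonucleotide reductase gene RnrS rose by 0.41 ± 0.084 (limma adjusted p = 0.00513). Syx1A, for synaptic vesicle fusion, rose by 0.31 ± 0.080 (limma adjusted p = 0.0198), not without mof 2 (0.0573), after recentring (0.24; 0.0662) or with quantile normalization (0.0621). The sex determination gene Sxl fell by 0.35 ± 0.088 (limma adjusted p = 0.0189), not without mof 2 or 3 (0.0509 to 0.0524). Sxl, Corp, futsch and moody lie on the X, where the median over all tested genes was -0.45, so Sxl fell less than that median. The heat shock gene Hsp83 rose by 0.61 ± 0.16 (limma adjusted p = 0.0225), not without control 5, mof 1 or mof 2 (0.055 to 0.0642). With the block 3 more genes passed: the heat shock gene Hsp26 (0.29; limma adjusted p = 0.256, blocked 0.0239), the cell death gene skl (0.31; 0.0518, blocked 0.0201) and the germ line gene aub (-0.47; 0.0933, blocked 0.00792). Without mof 5 skl (0.00987) and aub (0.0177) passed as well.

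Other lists in RNA-seq males had the following members rising and falling: MSL 2 and 3 (3 and 3 over the list alone), NSL 2 and 1 (4 and 2), sex determination 1 and 2, cell cycle 2 and 2, maternal 2 and 0 (1 and 0), neuron 1 and 1, glia 1 and 1. Hox, fat body and heat shock genes each had 1 rise, and so did midgut and germ line genes, which had 0 over the list alone. Ecdysone genes had 1 rise and 1 fall, epidermis 1 fall and yolk 1 fall, with 0 over the list alone. Early patterning, muscle, hemocyte, trachea, salivary gland and immune peptide genes had 0. With the replicate block the ribosomal list was also called (camera adjusted p = 0.205, blocked 0.0302; blocked adjusted p = 0.99 with an estimated correlation), giving 2 lists, as there were without control 5 or without mof 4. Medians and means differed in sign for the MSL (0.15 and -0.66), NSL (0.23 and -0.27), oxidative phosphorylation (0.044 and -0.042) and mitochondrial ribosomal (0.026 and -0.070) lists. They also did for cell death (0.090 and -0.0059), ecdysone (-0.0068 and 0.037), neuron (0.026 and -0.026) and midgut genes (0.019 and -0.0066). Oxidative phosphorylation, mitochondrial ribosomal, Hox, ecdysone, early patterning, neuron, glia, hemocyte, fat body, trachea, epidermis, midgut and salivary gland lists changed direction with the scaling. Ecdysone and early patterning turned with quantile normalization. For the others recentring moved all genes by 0.073, more than their medians, which alone turns them.

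In RNA-seq females 3 lists were called. Ribosomal genes had 84 of 89 above 0 with a median of 0.066 (camera adjusted p = 0.0212; adjusted p = 0.86 with an estimated correlation), lost without control 3 (0.281), control 4 (0.169) or mof 5 (0.628). Of 14 cell death genes 11 lay above 0, with a median of 0.27 (camera adjusted p = 0.0391; adjusted p = 0.853 with an estimated correlation) and 3 risen over the list alone. That call was lost without control 1 (0.0564), control 2 (0.058), control 4 (0.0524) or mof 4 (0.0988). Its TNF gene egr rose by 0.29 ± 0.067 (limma adjusted p = 0.023; blocked 0.0604), not without control 1 or 2 or mof 3, 4 or 5 (0.0557 to 0.0968). Hemocyte markers had 11 of 13 above 0 and a median of 0.24 (camera adjusted p = 0.0391; adjusted p = 0.853 with an estimated correlation), lost without control 1 (0.0537), 2 (0.058), 4 (0.0524), 5 (0.112) or mof 4 (0.0988), and with autosomal members only (0.0522). The maternal gene cort fell by 1.03 ± 0.26 (limma adjusted p = 0.0393), a call held only without control 5 (0.0528 to 0.114 otherwise) and lost with quantile normalization (0.077). The gene mRpS9 fell by 0.38 (limma adjusted p = 0.0467), not without control 1, 2, 3 or 5 or mof 1, 3 or 4 (0.0669 to 0.15). The count of 3 lists was 1 without control 2, 6 without control 3, 8 without mof 1, 5 without mof 3 and 1 without mof 4. With the block 6 were called, adding polymerase II factors (median -0.072; camera adjusted p = 0.102, blocked 0.027), muscle (0.194, blocked 0.0221) and epidermis (0.0917, blocked 0.0227). For these 3 the blocked adjusted p = 0.823 with an estimated correlation. The studied X list had a median of 0.041 and a mean of -0.098; it and the yolk list changed direction with the scaling.

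Among chromosome arms other than the X small shifts passed: 2R in TT-seq males, 0.021 ± 0.0055 (permutation adjusted p = 0.0238), 3R in RNA-seq males, -0.017 ± 0.0045 (0.0238), and chromosome 4 in RNA-seq females, 0.12 ± 0.024 over 96 genes (0.0476). Among genes with a mean of at least 50 the calls of 2R (permutation adjusted p = 0.155) and 3R (0.0714) were lost. No arm passed in TT-seq females. Chromosome 4 was -0.019 in TT-seq males (permutation adjusted p = 0.833) and 0.028 in RNA-seq males (0.571).

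In males the X fell least among the longest genes. In TT-seq males X minus autosomal medians were -0.69, -0.71 and -0.47 for the shortest, middle and longest of 3 equal classes of genes, with median lengths of 1070, 2620 and 10468 bp. In RNA-seq males the values were -0.61, -0.63 and -0.43. By level they were -0.56, -0.68 and -0.57 in TT-seq males and -0.48, -0.59 and -0.53 in RNA-seq males, from low to high. In females every value lay between -0.057 and 0.022. No test was set for these classes.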

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

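Of the tests in this part, those on scaling, level and overlapping genes for the X, on overlapping genes among the shared falls, and on v were chosen after the result was seen.

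What raised these results was a difference between the sexes in the effect of mof RNAi, each tested as an interaction. The X shift of males minus that of females was -0.62 in TT-seq and -0.53 in RNA-seq. In TT-seq the genes were na (-1.95), l(1)G0193 (-1.16), hfw (-0.91), schlank (-0.80) and roX2 (-2.55). The hfw call was lost without male control 3 or female mof 4 or 5 (limma adjusted p = 0.0501 to 0.0649). The schlank call was lost without male control 3 or 5, male mof 2 to 5, female control 1, 3, 4 or 5, or female mof 2, 4 or 5 (0.0525 to 0.125). In RNA-seq they were na (-1.73), RhoGAPp190 (-0.65), mys (-0.62), l(1)G0193 (-0.98), mof (-1.41), roX1 (-1.47) and roX2 (-2.60). All of these genes lie on the X, so the shared fall of the male X is part of each value. No library stood far from its group in the 40 groups of values tested for it (0 found). The values were the X shift, the depth and the levels of mof, roX1 and roX2. Whole profiles were not tested, and with 4 or 5 values only a wide gap is found. The RNA-seq female control with 11.9 M reads was not flagged.

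The fall of X genes in males was set against 3 technical explanations. Scaling moves X and autosomal genes of a library alike, and the difference within libraries was -0.62 in TT-seq and -0.55 in RNA-seq. Low read numbers do not account for it, since the class of genes with the highest level gave -0.57 and -0.53, nor do shared reads, since genes that overlap no other gene gave -0.63 and -0.57. Loss of X expression that depends on MOF in males is the biological explanation that the design gives. The contrast of mof RNAi with control within males gave these differences without use of the females. It does not part loss of MOF from off-target action of the RNAi, so that question stays open. The stronger fall of mof itself in males than in females in RNA-seq (-1.41) is another difference between the sexes.

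In RNA-seq 403 genes fell in both sexes, 303 autosomal and 100 on the X, while 13 rose in both. Shared reads do not account for the set, since 170 of the genes, or 42.2%, overlap no other gene, against 47.6% of the others. A stretch of another strain background stays open: 717 pairs of these genes lay 50 to 500 kb apart, against 646 in draws matched for arm and level (95% of draws 589 to 709; permutation p = 0.016). Promoters shared by divergent neighbours could bring part of it, as 18 divergent pairs fell together against 6.27 in draws (highest draw 14; permutation p = 0.001, the smallest possible). A direct action of maternal mof RNAi in both sexes also stays open, and no test here parts it from off-target action.

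The X gene v, which encodes tryptophan oxygenase, rose in all 4 tables although its mean lay below 50, and was picked after the values were seen. It went from 6.22 to 35.0 in TT-seq males, 5.61 to 42.8 in TT-seq females, 6.04 to 56.9 in RNA-seq males and 8.13 to 52.6 in RNA-seq females (limma adjusted p = 0.00492, 0.00372, 0.00246 and 0.0284). A changed stretch of the X would raise neighbours, but 0 of the 4 flanking genes passed upward in females by limma (0 at an unadjusted p below 0.05, 0 by edgeR), and the largest of their absolute changes was 0.52. That pattern is what a copy of v carried as a transgene marker could give; y, which may be carried with it, was 0.70 to 0.86 and passed in no table, though it did in RNA-seq males without control 3 (limma adjusted p = 0.0281) or with quantile normalization (0.0497).

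For each result of a test over many genes, 100 splits of the libraries were compared, the real one included. In TT-seq males 2 splits gave as many genes, the real one with 517 and another with 591. Over splits that ignore the replicate numbers the share is thus under 0.05. Since the numbers pair the samples, such splits are not interchangeable, so this share alone does not exclude chance. The 591 split puts control 1 and 5 with mof 1, 2 and 5, parts 1 pair of numbers and so follows the replicate numbers; with the number as a block the real split gave 1730, and the highest of the others that part all pairs 0. Over splits that ignore the numbers only 1, the real one, was as large for genes in TT-seq females (209, highest other 13), RNA-seq males (1890, 441) and RNA-seq females (618, 139). The same holds for the number of X genes called in TT-seq males (384, 66), TT-seq females (41, 0), RNA-seq males (894, 49) and RNA-seq females (105, 17). That number grows with all calls, so in females it does not show a share above that of autosomal genes. It also holds for the sex difference of genes in TT-seq (28, 2) and RNA-seq (455, 233). Among splits that part every pair, the blocked counts of the others were 0, against 850 in TT-seq females, 2843 in RNA-seq males and 752 in RNA-seq females. Only 16 splits part 5 pairs and 8 part 4 pairs, too few for a share under 0.05, so they cannot exclude chance either.

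The number of called lists was not set apart from chance. The splits counted lists of any kind, so they do not test a given list, such as the studied X genes in males. As many lists came from 98 of 100 splits in TT-seq males (2, highest other 16), 77 in TT-seq females (5, highest other 12), 99 in RNA-seq males (1, highest other 15) and 84 in RNA-seq females (3, highest other 15). What raised the counts of other splits was not tested. For genes between assays in males all 100 splits gave as many, since the real count was 0 (highest other 1).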

How the results depend on the processing

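The alternatives with edgeR, without overlapping genes and with autosomal list members were added after the data were seen, and every alternative set beforehand was run. Of the comparisons of single genes and lists, 3270 kept their side of the threshold and direction, 385 lost the call, 277 of these with 1 library left out, 42 gained it, 4 moved and 8 reversed. What depth limits was not tested on its own. In simulations of TT-seq males 64% of genes lowered by 1 were called, all of them autosomal with a mean of at least 50. For genes with lower means the share called was not simulated. Where no cause is given below, the cause was not tested.

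The replicate block gave 1730 genes in TT-seq males, 850 in TT-seq females and 2843 in RNA-seq males, and edgeR with the block 1554, 894 and 2995. Library weights gave 612 in TT-seq females, and recentring on autosomal genes 853 in TT-seq males. The blocked X shift was -0.62 in TT-seq males and -0.55 in RNA-seq males, with sign-flip permutation p = 0.0625 because 5 pairs allow no smaller value. The block changed no other call of a named gene or list than those given beside the results. In TT-seq females the X shift, near 0, reversed for genes with a mean of at least 50 (-0.0026), with means in place of medians (-0.0082) and for protein-coding genes (-0.0021).

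With an estimated correlation 0 lists were called in TT-seq males, 0 in TT-seq females, 0 in RNA-seq males and 0 in RNA-seq females; fry gave 1, 0, 2 and 0. The block gave 8 lists in TT-seq females, 2 in RNA-seq males and 6 in RNA-seq females. Autosomal members gave 7 in TT-seq males and 0 in RNA-seq males. Genes with a mean of at least 50 gave 1 list in RNA-seq females, and 1 arm in TT-seq males, 1 in RNA-seq males and 3 in RNA-seq females. With that filter the difference between length classes in RNA-seq males was 0.20 (0.18 with all tested genes). The male X shift between assays was -0.084 with that filter (permutation p = 0.0184) and -0.069 with the block (permutation p = 0.00794). Both tests take the assays as independent samples. Genes differing between the sexes in TT-seq were 48 with that filter, 214 after recentring and 461 with the block, and in RNA-seq 734 with the block.

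Signs of small values reversed for msl-3 in TT-seq females with quantile normalization (-0.0071), library weights (-0.067) and edgeR (-0.01), and for msl-1 (-0.018) and mle (-0.0029) in RNA-seq females with quantile normalization. Leaving out 1 library gave msl-3 in TT-seq females -0.047 to 0.076 and Clamp in RNA-seq females -0.074 to 0.0095, above 0 without control 4.

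With 1 library left out, gene counts were 248 to 553 in TT-seq males, 112 to 236 in TT-seq females, 1243 to 1809 in RNA-seq males and 455 to 615 in RNA-seq females. The X shift was -0.63 to -0.61 in TT-seq males, -0.57 to -0.53 in RNA-seq males, -0.0040 to 0.011 in TT-seq females and -0.023 to -0.0075 in RNA-seq females. The odds ratio of X falls was 1.11 to 1.99 in TT-seq females. Lists numbered 1 to 6 in TT-seq males, 4 to 7 in TT-seq females, 1 to 2 in RNA-seq males and 1 to 8 in RNA-seq females. The X shift between assays in males was -0.083 to -0.051, and genes differing between the sexes in TT-seq were 5 to 64. The libraries that moved these counts are named beside each result.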

Other observations

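The tests of Y reads were chosen after the data were seen.

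Y genes together took more reads in males after mof RNAi. In TT-seq males they went from 9.77 ± 1.80 reads per M reads (SD, n = 5) to 18.0 ± 2.54 (n = 5; permutation p = 0.00794, the smallest possible), and in RNA-seq males from 9.78 ± 1.34 to 15.4 ± 2.64 (permutation p = 0.00794). In both assays every mof RNAi library lay above every control. The dynein heavy chain gene kl-5, needed for male fertility, rose in TT-seq males by 1.68 ± 0.40, from 29.2 ± 13.0 to 91.1 ± 31.4 (limma adjusted p = 0.0302), but not without control 1 or mof 1, 2, 3 or 4 (0.0532 to 0.0859). In RNA-seq males it rose by 1.59 ± 0.47, from 44.3 ± 22.4 to 121 ± 49.8 (limma adjusted p = 0.0386), but not without control 2 or 3 or mof 1, 2, 3 or 4 (0.0516 to 0.0975), nor after recentring on autosomal genes (0.0504). The other Y gene tested in the list, FDY, was 0.58 in TT-seq males (limma adjusted p = 0.195) and 0.34 in RNA-seq males (0.154). In females fewer reads were assigned to Y genes. In TT-seq there were 1.30 per M reads in controls and 0.98 after mof RNAi (permutation p = 0.0159). In RNA-seq there were 0.461 and 0.506 (permutation p = 0.714). Where these few female reads come from was not tested, so they do not show expression of Y genes in females or a change in it. The male and female directions in TT-seq were not compared by a test.

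Genes that fell in both sexes in RNA-seq were shorter than the others, with a median length of 2019 against 2709 bp. Their median level was 220 against 471. That level averages control and mof RNAi libraries, so the fall itself accounts for part of the gap. They had a divergent neighbour within 1 kb in 50.9% of cases, against 34.0% of other genes. Their median fold change was -1.01 in males and -1.05 in females. Of those tested in TT-seq, 395 of 397 lay below 0 in females and 397 of 398 in males.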
